A study of Mus musculus with 40 samples.

How the data were processed

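The series measured where DNA ends made by the RAG endonuclease joined to other breaks in mouse progenitor B cells. RAG cuts beside a recombination signal sequence (RSS), which holds a heptamer with the consensus CACAGTG and a nonamer with the consensus ACAAAAACC, separated by a short or a long spacer. In high-throughput genome-wide translocation sequencing, a primer reads out of a chosen break, the bait, and the sequence joined to it, the prey, is mapped. Per the labels, 40 samples were collected in 18 groups. Processed junction tables of 3 of these samples were used here, IgH-AB replicate 2, RSSJ-chr1-12S replicate 1 and cRSS-chr1 replicate 1, and the other samples were not analysed here. Each of those groups therefore had 1 library here.

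Per the labels, the 3 libraries came from genomic DNA of v-Abl transformed pro-B cell lines, which are arrested lines in which an inhibitor of the Abl kinase induces RAG. The lines lacked ATM, a kinase of the DNA break response, and carried a Bcl2 transgene that favours survival. They were grown with 15% serum and treated with 3 uM STI-571, the Abl inhibitor, for 4 days. Sequencing libraries were made by linear amplification and read on an Illumina MiSeq, per the series design text and the labels. The submitters' processing notes name Bowtie2, without a version, and mm9. The label of the IgH-AB library names a modified mm9 reference. The junction caller, its filters and any removal of duplicate reads are not given in the sources used here.

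Each deposited table holds 1 record per junction, and per the file headers it gives the prey chromosome, the prey base next to the break, the strand, the ends of both alignments and the read. The deposited values are positions, strands and read sequences, a unit of the kind other, with no normalisation by the authors. Junction counts were made here by counting records. Repeated reads were kept as deposited, and molecules carried no identifiers in the tables, so intervals and floors cover counting error only. The prey sequence of each junction was compared with mm9 (NCBIM37) at the deposited position, and at least 90% of the first 30 bases matched for 99.6%, 99.3% and 98.7% of the junctions of the IgH-AB, RSSJ-chr1-12S and cRSS-chr1 libraries.

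In the IgH-AB table, chromosome 12 lacked 53040 bp of mm9. A search of mm9 with prey sequences found 55 positions without a shift up to 114667229 and 96 positions shifted by 53040 bp above that, and 2 with another shift. The bait sequence carried the same shift. Positions in this library are therefore given as mm9 positions from that match, while distances from the bait were taken in the table's own coordinates. Genes and segments came from the gencode vM1 annotation of mm9. Names of 75 of 112 Igh V segments came through synonyms in a RefSeq table of GRCm38.p6, from which no coordinates were used. Antigen receptor loci were taken as annotated segments less than 1 Mb apart, with 5 kb either side.

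Windows were centred on the median bait end. The bait of the RSSJ-chr1-12S library is a named construct with no genome position in the table, so its windows were centred on the median of its largest prey cluster, a choice made after seeing the data. Shares carry exact Clopper-Pearson 95% intervals, and for a share of 0 the floor is 3 counts of the total. Strands were compared by two-sided exact binomial tests. Counts above and below the bait or cluster centre left out junctions within 1 kb of it. CAC, the first bases of the heptamer, was sought in mm9 exactly at the break, in the prey or ending just outside it, and again at places 10 to 50 bp away. Recurrent positions near the bait needed at least 3 junctions at 1 base and strand outside 1 kb of the bait. For the RSSJ-chr1-12S library, positions within 1 kb of the cluster centre were kept. Prey hotspots were 10 kb bins outside 1 Mb of the bait with at least 3 junctions and a Poisson adjusted p under 0.05 against the mean of the other chromosomes. Junctions outside 1 Mb of the bait and outside receptor loci were counted within 2 kb of annotated transcription start sites and compared with 1000 random shifts along their chromosomes, one-sided. Libraries were compared by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment within each family. The comparison of Igk shares and the nonamer scores were added after seeing the data. Nonamer matches were scored 12 or 23 bases after the heptamer, allowing 1 base more or less, against 10000 random CAC sites.

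Named genes followed a rule set before the data were examined: every Igh D and J segment and the 15 Igh V segments with the most junctions, each receptor locus with its leading segments, up to 10 hotspots per library outside receptor loci, the 10 leading positions near each bait, the bait neighbourhood genes, and members with at least 2 junctions of 3 fixed lists (early B lineage genes, lymphoma genes, long late replicating genes). Alternatives fixed before the data were examined counted each prey base and strand once, required a prey alignment of at least 50 bp, and changed windows, denominators, motif rules, bins and minimum counts. Further alternatives, chosen after seeing the data, counted distinct fragments and left out telomere repeat prey. For the RSSJ-chr1-12S library, 1 prey item and the results that rest on it, its start site comparison, strand counts on other chromosomes, number of hotspots and CAC share outside 1 Mb among them, are not reported here, while its records stay in that library's totals.

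The procedures were tested on simulated data. In simulations the size of each library's junctions on other chromosomes, 20 of 20 planted hotspots were recovered at 3, at 5 and at 10 junctions, with 0 false calls. At most 0.00246 junctions per bin were expected in the real libraries, so any bin with 3 passes and this recovery was fixed in advance. Simulated positions were uniform, without repeated reads or repeat sequence. The 0 false calls therefore do not carry over to libraries that hold either. Without planted enrichment the start site test called 6%, 6% and 3% of 100 runs for the IgH-AB, RSSJ-chr1-12S and cRSS-chr1 sizes, and with 20% of junctions planted near start sites it called 100% for each. Among 2000 simulated junctions with 990 planted at CAC, 1009 had CAC at the break. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9 were used.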

Results

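Junctions were measured in 1 library for each of 3 baits in ATM-deficient v-Abl pro-B lines, so no spread between replicates could be given. The IgH-AB library (replicate 2) held 8244 junctions, read out of a break at the Igh D segment Ighd1-1. The RSSJ-chr1-12S library (replicate 1) held 678 junctions, read out of a construct that carries an RSS with a 12-base spacer. The cRSS-chr1 library (replicate 1) held 3106 junctions, read out of a cryptic RSS, an RSS-like sequence outside the receptor loci, on chromosome 1. The IgH-AB records came from 5060 distinct reads, 773 prey positions and 3329 distinct fragments. The RSSJ-chr1-12S records came from 677 distinct reads, 289 positions and 671 fragments. The cRSS-chr1 records came from 3106 distinct reads, 631 positions and 2513 fragments. Identical repeated reads were thus nearly confined to the IgH-AB library. A count of 0 allowed a share of up to 0.0364%, 0.442% and 0.0966% in these libraries, in that order.

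The first question, posed by the series title, was whether RAG activity stays near the bait. In the IgH-AB library 88.2% of junctions (95% interval 87.5 to 88.9) lay within 1 Mb of the bait break, and 92.9% (92.3 to 93.4) lay in the Igh locus. In the cRSS-chr1 library 79.6% (78.1 to 81.0) lay within 1 Mb of the bait, nearly all of them at 1 site 52.8 kb away. In the RSSJ-chr1-12S library 78.9% (75.6 to 81.9) lay within 1 Mb of the centre of a cluster on chromosome 4, around Jun, a subunit of the AP-1 transcription factor, and Fggy. That window was placed on the library's largest prey cluster, so its share was high by construction. It does not show that prey stayed near the bait, whose position is not known. Chromosome 1, which the group name gives, held 4 junctions of that library, or 0.590% (0.161 to 1.504).

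The shares rose with the window in the IgH-AB library, from 29.0% within 10 kb to 62.0% within 100 kb and 85.2% within 500 kb. In the cRSS-chr1 library they rose from 1.32% within 10 kb to 79.5% within 100 kb. Each library's window was nearly empty in the other libraries. The chromosome 4 window held 0 junctions in the IgH-AB library and 0 in the cRSS-chr1 library. The chromosome 1 window held 2 junctions of the IgH-AB library and 0 of the RSSJ-chr1-12S library, and the Igh window held 3 of the cRSS-chr1 library and 0 of the RSSJ-chr1-12S library. When each prey base and strand was counted once, the shares within 1 Mb were 25.7% in the IgH-AB library, 67.8% in the RSSJ-chr1-12S library and 10.3% in the cRSS-chr1 library.

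**Figure D1:**
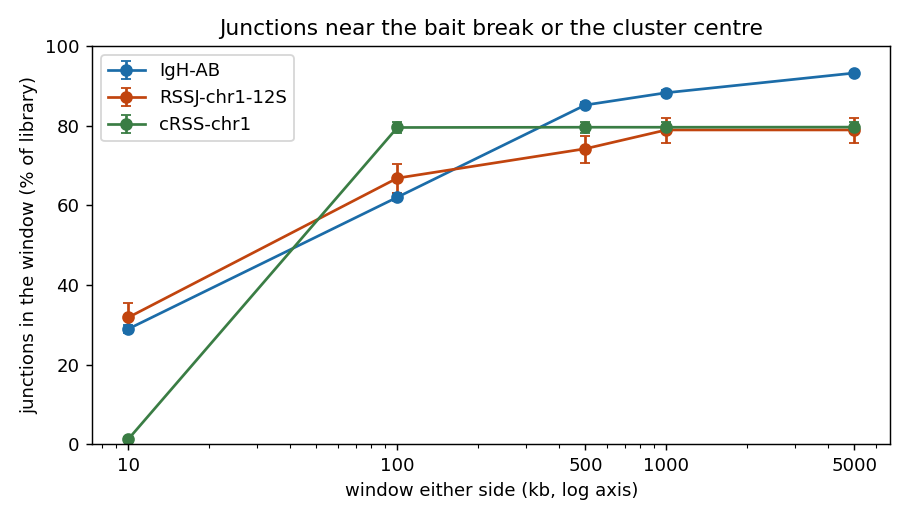
Percent of each library's junctions (vertical axis) within windows of 10 to 5000 kb either side (horizontal log axis) of the bait break, or of the chromosome 4 cluster centre for RSSJ-chr1-12S; bars are exact 95% intervals, 1 library per line. The cRSS-chr1 line rises between 10 and 100 kb, from 1.32% to 79.5%.

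The strand of the prey was used to ask whether joining near a bait had a direction. In the IgH-AB library prey at coordinates above the bait, the side of the V segments, was almost all on the minus strand. There, 72 junctions were plus and 5402 minus within 1 Mb and outside 1 kb, a plus share of 1.32% (1.03 to 1.65), or 12.6% with each prey base and strand counted once and 3.31% by distinct fragments. In the cRSS-chr1 library the strand was the opposite one, with 2426 plus and 3 minus junctions above the bait, a plus share of 99.9% (99.6 to 100.0), but nearly all of them at 1 site. These are strands of mm9 and were not set against the strand on which each bait was read. Opposite strands in these 2 libraries therefore do not show opposite directions of joining. In the RSSJ-chr1-12S library both sides of the chromosome 4 centre were minus. Outside 1 kb of the centre, 1 junction was plus and 174 minus below it (exact binomial adjusted p = 1.38e-50), and 2 were plus and 152 minus above it (exact binomial adjusted p = 1.68e-42). The position of this library's bait is not known, so these tests show no direction from a bait.

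On other chromosomes the IgH-AB library had 268 plus and 272 minus junctions (exact binomial adjusted p = 0.985). The cRSS-chr1 library had 338 plus and 264 minus (exact binomial adjusted p = 0.00352). Without telomere repeat prey, a choice made after seeing the data, it had 185 plus and 155 minus (exact binomial adjusted p = 0.133). Within 1 kb of the IgH-AB bait, in the table's own coordinates, the strand turned to 1556 plus and 206 minus. Ighj4, counted with 500 bp either side, held 1489 plus and 186 minus. Within 1 kb of the cRSS-chr1 bait the strand turned too, to 2 plus and 39 minus.

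The RSS heptamer was sought at the break to see which prey ends RAG could have cut. In the IgH-AB library 93.8% (93.2 to 94.5) of junctions within 1 Mb and outside 1 kb had CAC at the break, 93.5% with CAC as the first prey bases. In the RSSJ-chr1-12S library 40.7% (36.6 to 45.0) of all 535 junctions within 1 Mb had it, 103 in the prey and 115 just outside. There the 206 junctions within 1 kb of the cluster centre were kept, so the populations are not alike. In the cRSS-chr1 library 21.5% (19.9 to 23.2) of junctions within 1 Mb and outside 1 kb had CAC at the break, 521 of 523 just outside the prey. In the same junctions 96.1% (95.2 to 96.8) had CAC within 5 bp. Shifted places gave means of 3.41%, 4.46% and 2.52% at the break, but since few positions held most junctions, single shifted places reached 82.5%, 13.3% and 29.9%, the last above the cRSS-chr1 share at the break. For CAC within 5 bp in the cRSS-chr1 library they gave a mean of 27.4% and reached 95.02%.

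Outside 1 Mb the shares were 19.9% (17.5 to 22.6) in the IgH-AB library, against a mean of 4.02% and a highest value of 15.8% at shifted places, and 10.1% (7.86 to 12.7) in the cRSS-chr1 library, against 2.73% and 5.52%. Without telomere repeat prey the cRSS-chr1 share was 17.9% (14.1 to 22.3), against 3.77% and 7.56%. These shares were not taken without receptor loci. Of the junctions outside 1 Mb, Igh held 41.8% and Igk 5.47% in the IgH-AB library, and Igk held 24.9% in the cRSS-chr1 library. CAC there can therefore come from RSSs of receptor segments. Counted once per prey base and strand, the IgH-AB share outside 1 Mb was 9.95% (7.62 to 12.7), against a highest value of 8.20% at shifted places, inside that interval. Counted once per prey base and strand, the IgH-AB share within 1 Mb was 46.4% (38.2 to 54.6), against a mean of 4.38% and a highest value of 19.2% at shifted places, and the cRSS-chr1 share was 8.33% (2.32 to 19.98), against 4.65% and 10.4%.

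**Figure D2:**
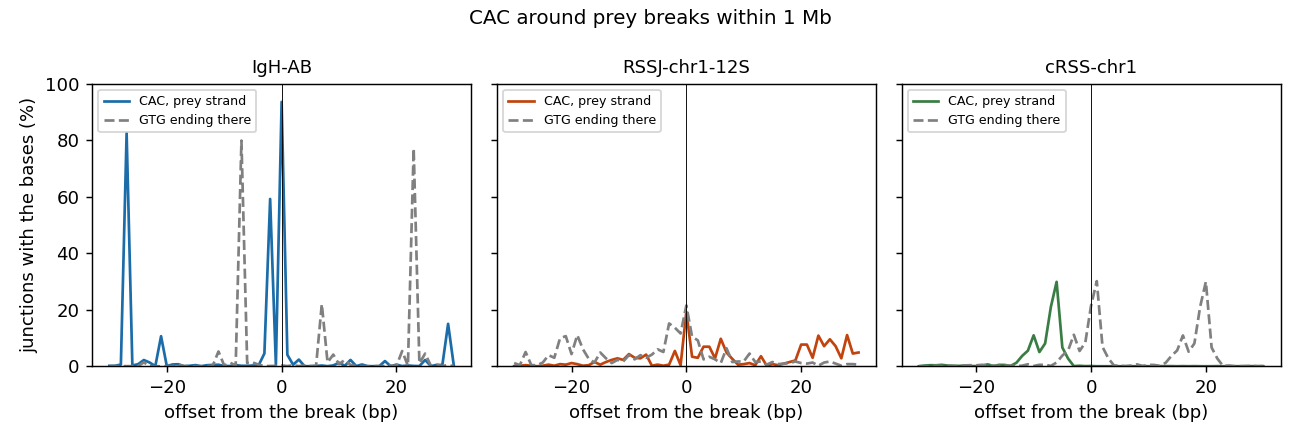
Percent of junctions within 1 Mb (vertical axis) with CAC starting on the prey strand, or GTG ending, at each offset from the break in bp (horizontal axis, 0 is the break), 1 panel per library. Junctions within 1 kb of the bait are left out for IgH-AB and cRSS-chr1, and kept around the cluster centre for RSSJ-chr1-12S. At the break the prey strand value is 93.5% in IgH-AB, 19.3% in RSSJ-chr1-12S and 0.0823% in cRSS-chr1; other peaks come from the bases around the few leading sites.

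Direct joins, with neither extra bases nor overlap, made up 92.1% of IgH-AB junctions within 1 Mb, 16.4% of RSSJ-chr1-12S junctions and 18.9% of cRSS-chr1 junctions. Extra bases were present in 3.11%, 40.7% and 59.9%. These shares kept junctions within 1 kb of the bait or cluster centre. The joined ends differed between libraries: within 1 Mb and outside 1 kb, the prey began with CAC at 93.5% of IgH-AB breaks and 0.0823% of cRSS-chr1 breaks. Neither these shares nor those of CAC at the break therefore compare how much RAG cut in each library.

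The IgH-AB library shows at which Igh segments the joined prey ends lay. Of the junctions at V segments, 88.9% (88.0 to 89.8) lay at the segment end with prey reading away from the segment, so in these the RSS side of the break was joined and not the V segment. Counted with 500 bp either side, V segments held 5011 junctions, 60.8% (59.7 to 61.8) of the library, J segments 1677 or 20.3% (19.5 to 21.2), and D segments 6. Ighv5-2, the V segment at chromosome 12 positions 114816715 to 114817201, alone held 2635 junctions, or 32.0% (30.96 to 33.0) of the library and 52.6% of the V junctions. Its leading break lay at 114816714, with 2588 junctions and the heptamer CACAATG. The V segments nearest the bait dominated: the nearest 28 segments, between 114812453 and 115272302, held 90.2% (89.3 to 91.0) of V junctions, and the farthest 28 held 1.60% (1.27 to 1.98).

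After Ighv5-2 came Ighv2-3 with 538 junctions, Ighv5-4 with 519, Ighv2-2 with 242, Ighv2-9 with 154 and Ighv2-6 with 121. Ighv2-5 had 95, Ighv7-3 had 60, Ighv1-47 had 59, Ighv8-12 had 54, Ighv5-6 had 51, Ighv10-1 had 50, Ighv5-9 had 44 and Ighv7-1 had 36. Ighv1-9 completed the 15 with 33. In all, 60 of 112 annotated V segments had junctions. The Ighv5 family held 65.8% (64.5 to 67.1) of V junctions and the Ighv2 family 23.03% (21.9 to 24.2), while the large Ighv1 family, with 55 members, held 3.85% (3.34 to 4.42). Of the 3297 Ighv5 junctions, 2635 lay at Ighv5-2, and without that segment the Ighv2 family, with 1154, held more. Of the V junctions, 97.5% (97.1 to 97.9) lay within 10 bp of a segment end and 99.3% were on the minus strand.

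Ighj4, at 114666725 to 114666778, held 1675 junctions, 20.3% (19.5 to 21.2), and Ighj3 held 2. Ighd1-1, at 114720381 to 114720403, held all 6 D junctions by the 500 bp rule, but 0 of them lay within 100 bp of it. Ighj1, Ighj2 and 17 of the 21 annotated D segments lie in the stretch between Ighj3 and Ighd1-1 that the table's reference lacks, so their 0 counts carry no information. The other D segments, Ighd3-1, Ighd5-1 and Gm16968, had 0 junctions. By distinct fragments the Ighv5-2 share was 11.2%, and with each prey base and strand counted once the V share was 15.1%.

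**Figure D3:**
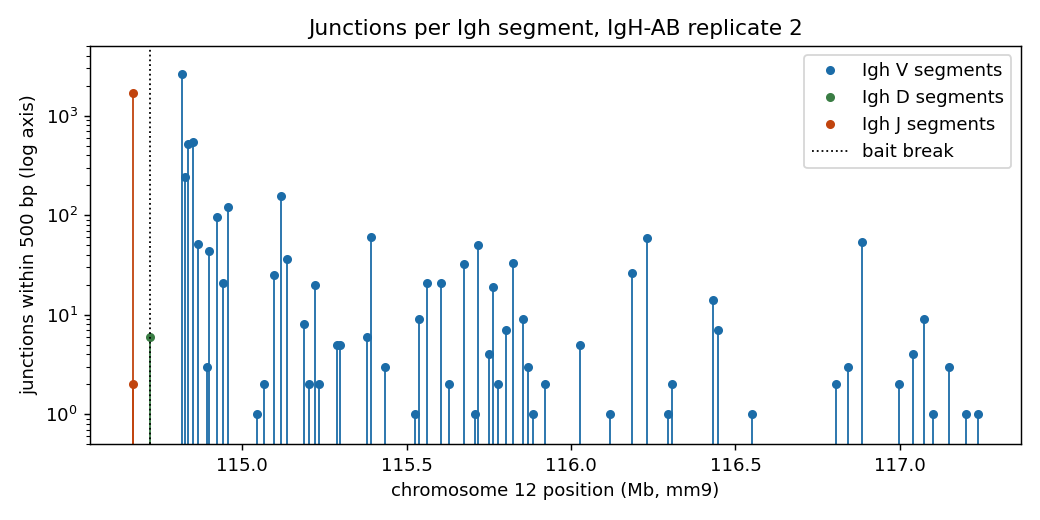
Junctions within 500 bp of each Igh segment (vertical log axis) against chromosome 12 position in Mb of mm9 (horizontal axis) in the IgH-AB library, 1 point per segment with at least 1 junction. Ighv5-2, with 2635, is the highest point, and V counts are lower at greater distance from the bait break.

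Receptor loci other than Igh were asked for as prey because their RSSs are the known RAG targets elsewhere. Igk, the kappa light chain locus, was the one such locus hit repeatedly in all 3 libraries. It held 53 IgH-AB junctions, 0.643% (0.482 to 0.840), 40 RSSJ-chr1-12S junctions, 5.90% (4.25 to 7.95), and 158 cRSS-chr1 junctions, 5.09% (4.34 to 5.92). The leading segments were Igkj1 with 10 and Igkj5 with 5 in the IgH-AB library, Igkv6-25 and Igkj2 with 3 each in the RSSJ-chr1-12S library, and Igkj2 with 14 and Igkj4 with 13 in the cRSS-chr1 library. The Tra/Trd locus held 9 IgH-AB junctions, all at 1 base beside Trav15-1-dv6-1, and 0 in the other libraries. Igl held 1, 1 and 2 junctions, and Trb and Trg held 0 in each. Igh held 8 cRSS-chr1 junctions, 5 of them telomere repeat prey, and 0 RSSJ-chr1-12S junctions. Counted once per prey base and strand, the Igk shares were 5.30%, 13.1% and 21.2% in the IgH-AB, RSSJ-chr1-12S and cRSS-chr1 libraries, and by distinct fragments 1.53%, 5.96% and 6.29%. Among junctions beyond 1 Mb, Igk held 5.47% in the IgH-AB library and 24.9% in the cRSS-chr1 library.

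Recurrent sites near each bait, or near the chromosome 4 cluster centre, were sought as off-target cryptic RSSs. In the cRSS-chr1 library a single cluster at chromosome 1 positions 167572073 to 167572150 held 2424 junctions, 78.0% (76.5 to 79.5), at 41 positions and in 1835 fragments. It lay between Mpzl1 and Rcsd1, 6999 bp from Rcsd1, and the sequence outside the prey, 167572039 to 167572077, began on the minus strand with the heptamer CACGGTG. The bait heptamer, CACAGTG, lay on the plus strand from 167519295, so the heptamers pointed toward each other. Neither had more than 5 of 9 nonamer bases at either spacer.

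In the RSSJ-chr1-12S library 13 clusters held 403 junctions between 94718166 and 95533797 on chromosome 4, all on the minus strand. The largest, 192 junctions or 28.3% (25.0 to 31.9), lay in an intron of BC042782 at 94772960 to 94773005, beside CACAGCG. Its flank matched 7 of 9 nonamer bases at a 12-base spacer, which 0.920% of random CAC sites reached. This cluster lay at the window centre itself, and junctions within 1 kb of that centre were kept here. Whether it lies at the insertion site of the bait construct, and so is not off-target, was not tested. Clusters in an exon of Jun held 45 junctions at 94718870 and 16 at 94718176, and the neighbourhood of Jun with 5 kb either side held 119. Other clusters in BC042782 held 27 at 94719874 and 25 at 94730663. A site 120 bp from Fggy, 95224078, held 22 junctions, and a site in an intron of Gm12708, 94866047, held 19, both beginning with CACTGTA and matching 7 of 9 nonamer bases at a 23-base spacer, which 0.910% of random sites reached. Of the 13 clusters, only 1 reached 7 bases at a 12-base spacer and 2 at a 23-base spacer; the 2 Jun clusters did at neither.

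In the IgH-AB library 15 clusters outside annotated segments held 720 junctions. The largest of these, 114722366 with 231 junctions, lay 1.96 kb from the bait and began with CACAGTG, and 114721411 held 135. Of the 15, 3 matched at least 7 of 9 nonamer bases at a 23-base spacer, as did all 24 V segment clusters. The 3 were 114811137 with 74 junctions, 1316 bp from Ighv2-1, 115595971 with 15, 1 bp from Gm15449, and 115693837 with 13. Each matched 8 bases, the median of the V segment clusters. They are therefore not shown to be cryptic, and whether they are RSSs of V segments missing from the annotated list was not tested. A site at 114386889, 3174 bp from Crip2 and outside the locus, held 17 junctions and began with CACGGTG.

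**Figure D4:**
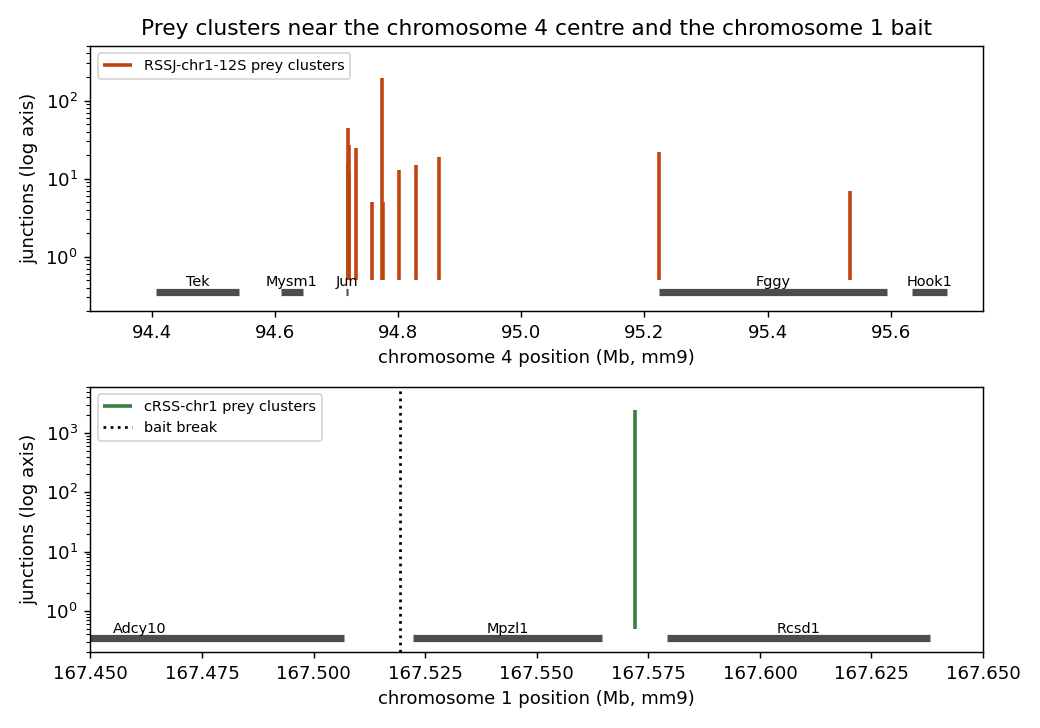
Junctions per prey cluster (vertical log axis) against position in Mb of mm9 on chromosome 4 for RSSJ-chr1-12S (top) and on chromosome 1 for cRSS-chr1 (bottom); grey bars are selected genes, drawn at an arbitrary height. The top panel spreads from Jun to Fggy with a peak of 192, and the bottom panel has 1 cluster of 2424 beyond the bait break.

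Away from the bait, recurrent prey of the IgH-AB library was rare outside receptor loci. Of 30 hotspots, 26 lay in receptor loci, most of them in Igh, the bait's own locus, which extends beyond the 1 Mb window. Igk held 4 of the 26, and the Tra/Trd site beside Trav15-1-dv6-1 was another. With each prey base and strand counted once, 5 hotspots were left. The hotspots outside receptor loci were 7 junctions at chromosome 13 position 30401384, 26926 bp from Agtr1a, an angiotensin receptor gene, and 3 junctions each in an exon of Rnf19a, near AC121600.1, and in overlapping introns of Gm17683 and 9330159M07Rik. Each of these lay at 1 base and strand.

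Hotspots of the RSSJ-chr1-12S library included 2 in Igk and 1 with 3 junctions 13939 bp from Rpia. The cRSS-chr1 library had 55, of which 16 lay in Igk and 37 were mostly telomere repeat prey. The leading ones outside receptor loci were of that kind, with 15 junctions near CT010480.1, 13 near Gm13173, 10 near Jazf1 and 9 each near Gng4 and Gm14496 and in introns of Slc14a2 and Ppp1r9a, then 8 each in introns of Ttc21b and Flt1 and 7 near Plk2. Telomere repeat prey was placed in 104 bins on 20 chromosomes, and whether these reads match mm9 at 1 place only was not tested. The named genes therefore mark where repeat reads aligned, and recurrent breaks near them are not shown. Without telomere repeat prey 17 bins passed the threshold.

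Side by side, how much prey left the bait neighbourhood depended on how junctions were counted, and bait, group and library change together, so the tests compare these libraries and not conditions. Identical repeated reads, nearly confined to the IgH-AB library, also make the counted records unlike between libraries. The share within 1 Mb was 8.66 percentage points higher in the IgH-AB library than in the cRSS-chr1 library (Fisher's exact adjusted p = 4.16e-30), but by distinct fragments the shares were 74.1% and 74.9%, a difference of -0.824 points (Fisher's exact p = 0.486). Leaving out telomere repeat prey, 277 junctions in the cRSS-chr1 library and 3 in the IgH-AB library, also closed most of the 8.66-point gap. The chromosome with the most junctions held 93.4% in the IgH-AB library, 79.2% in the RSSJ-chr1-12S library and 80.6% in the cRSS-chr1 library. The first differed from each of the others (Fisher's exact adjusted p = 2.46e-30 and 1.34e-81). Igk shares differed between IgH-AB and RSSJ-chr1-12S (Fisher's exact adjusted p = 5.81e-21) and between IgH-AB and cRSS-chr1 (Fisher's exact adjusted p = 3.77e-47), and in the same direction with each prey base and strand counted once (Fisher's exact p = 3.68e-05 and 1.37e-19). CAC at the break, over all junctions, was present in 83.8%, 34.7% and 19.0% in that order of libraries. Counting each prey base and strand once turned the difference in the main chromosome's share between the IgH-AB and RSSJ-chr1-12S libraries from 14.2 to -32.7 percentage points, and that in CAC from 49.1 to -11.8.

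RAG2 binds a histone mark of active start sites, so off-target prey was compared with annotated start sites. In the IgH-AB library 58 of 500 junctions, 11.6% (8.93 to 14.7), lay within 2 kb of a start site against 37.3 in random shifts (permutation adjusted p = 0.0120, one-sided). In the cRSS-chr1 library 49 of 466 did, against 36.6 (permutation adjusted p = 0.149), and without telomere repeat prey 25 of 194 did, against 15.4 (permutation adjusted p = 0.0360).

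The fixed gene lists held few junctions. The 20 early B lineage genes had 0 junctions in each library, which allows up to 0.0364% in the largest. The 13 lymphoma genes had 2, 1 and 1 junctions in the IgH-AB, RSSJ-chr1-12S and cRSS-chr1 libraries, none with 2 in a gene. The 13 long late replicating genes had 6, 0 and 1, with 3 of the 6 in Csmd1, at chromosome 8 positions 15892537 to 17535586.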

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

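All tests in this part were chosen or given their final form after the results they bear on had been seen.

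Telomere repeat prey made up 277 junctions, 8.92% (7.94 to 9.98) of the cRSS-chr1 library, a signal no comparison had asked for, against 3 in the IgH-AB library and 0 in the RSSJ-chr1-12S library. An earlier form of the test asked whether a few molecules had been copied, and counted 249 distinct pairs of bait end and prey fragment end. That count cannot decide, since the prey end of a repeat read depends on where the repeat was aligned. Copies of a few molecules stay open, though the reads had 131 distinct lengths. The test that replaced it had bounds set after the reads had been examined. It found that 83.4% carried 1 of 2 sequences after the most common bait end, GGCCCTAA or GACCCTAA. The reads were chosen for holding the repeat, so mainly the 2 leading bases and the base at which the repeat began could vary. A candidate explanation, and no more, is 1 or a few joining events carried by many molecules, while a preferred joint made repeatedly stays open. Priming away from the break is argued against by the 99.6% of bait ends within 10 bp of the most common one, while breaks inside internal repeat tracts stay open: 100% lay on the CCCTAA strand, but a few joining events would show 1 strand whatever their origin. No biological explanation was tested, since the design gives no group for it.

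The library named for chromosome 1 had 535 junctions within 1 Mb of a chromosome 4 centre, a place the labels do not give. For a region that breaks often in all these lines, the shares were 0% in both other libraries. The exact 95% upper limits were 0.0447% and 0.119%, and the floors of 3 counts 0.0364% and 0.0966%. The bound of 0.1% set for the shares (loosened once these limits had been seen, then restored) lies between the limit and the floor of the cRSS-chr1 library. A share of about that size is at the edge of that library's depth. These shares cannot decide the question, because windows around other baits were nearly empty too. The Igh window, with 88.2% of IgH-AB junctions, held 0.0966% of cRSS-chr1 junctions and 0 RSSJ-chr1-12S junctions, also below that bound. Wrong alignment is argued against by a search of mm9 with all stretches of 20 bases of the prey reads, in which 0.187% (upper limit 1.04%) matched another place at least as well. For a bait on chromosome 1, the upper limit of the chromosome 1 share, 1.504%, lay below that chromosome's 7.43% of the genome's length. This cannot decide the question, because chromosome 4 held 79.2% of the junctions. Chromosome 2 also lay below its own length share, with 0.442% against 6.85%. What the counts do show is that chromosome 1 held 4 junctions here. In the IgH-AB and cRSS-chr1 libraries the bait's chromosome held 93.4% and 80.6%. A different insertion site or a sample under another name stays open, and neither was tested.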

How the results depend on the processing

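Counting distinct fragments and leaving out telomere repeat prey were chosen after the data had been seen; the other alternatives were set before the data were examined. Of 196 alternative values for 43 results, 126 stayed within the interval of the reported value, near a reported count, or on the same side of a test's threshold (unadjusted p of 0.05); 62 moved, 1 weakened, 2 strengthened and 5 reversed.

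Counting each prey base and strand once moved the most values, 23 of 40, since few positions held most junctions. Shares within 1 Mb became 25.7% (IgH-AB), 67.8% (RSSJ-chr1-12S) and 10.3% (cRSS-chr1), and shares on the main chromosome 35.8%, 68.5% and 14.7%. CAC within 1 Mb became 46.4%, 36.2% and 8.33%, and 9.95% elsewhere in IgH-AB. The Igh share became 31.8% in IgH-AB and 0.792% in cRSS-chr1, and the Igk shares 5.30%, 13.1% and 21.2%. V segments held 15.1%, J segments 4.53% and Ighv5-2 1.81%. IgH-AB had 5 hotspots. The plus share above the IgH-AB bait was 12.6%, against 3.31% by distinct fragments, and still passed its test. That below the bait was 25% and no longer passed its test. IgH-AB minus RSSJ-chr1-12S reversed to -32.7 percentage points for the main chromosome and -11.8 for CAC. RSSJ-chr1-12S minus cRSS-chr1 for Igk, 0.813 points over all junctions and not past its test, reversed to -8.09 points and passed. Recurrent positions cannot be counted this way.

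Distinct fragments gave 74.1% (IgH-AB) and 74.9% (cRSS-chr1) within 1 Mb, so that their difference reversed to -0.824 points, without passing its test. The main chromosome held 84.5% and 76.2%. In IgH-AB, CAC was at 88.1% of breaks within 1 Mb, Igh held 83.1%, Igk 1.53%, V segments 49.8%, J segments 14.5% and Ighv5-2 11.2%, and in cRSS-chr1 Igk held 6.29%. RSSJ-chr1-12S minus cRSS-chr1 for Igk reversed to -0.326 points, without passing its test.

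With prey alignments of at least 50 bp, the share within 1 Mb was 89.4% in IgH-AB and 76.2% in cRSS-chr1, and that on the main chromosome 95.05% and 77.0%. In IgH-AB, CAC elsewhere was 23.3%, Igh 94.6% and V segments 62.6%, and Igh in cRSS-chr1 was 0.0564%.

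Without telomere repeat prey, cRSS-chr1 had 87.4% within 1 Mb, 88.0% on chromosome 1, 0.106% in Igh and 17 hotspots, and its start site ratio, 1.62, passed its test. Its junctions elsewhere then had CAC at the break in 17.9%, CAC within 5 bp in 67.8% and CACA in 12.6%. Without junctions within 1 kb, IgH-AB had 85.1% within 1 Mb and 91.7% on chromosome 12. Of junctions beyond 1 Mb, Igh held 41.8% in IgH-AB and 1.26% in cRSS-chr1, and Igk 5.47% and 24.9%.

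CAC within 5 bp was found within 1 Mb in 99.4%, 95.9% and 96.1%, and elsewhere in 64.2% (IgH-AB) and 41.2% (cRSS-chr1). CACA was found within 1 Mb in 89.8%, 19.1% and 0%, and elsewhere in 16.8% (IgH-AB) and 7.098% (cRSS-chr1). With at least 5 junctions, hotspots numbered 18 in IgH-AB and 23 in cRSS-chr1, and recurrent positions 20 in RSSJ-chr1-12S. The start site ratio of cRSS-chr1 within 10 kb, 1.29, passed its test. Apart from effects built into an alternative, such as fewer junctions or a looser motif, the cause was not tested.

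No paired analysis was possible because 1 library per group was analysed here, although the labels share replicate numbers; leaving out a replicate was likewise impossible. Depth limited the RSSJ-chr1-12S library most, with 678 junctions and a floor of 0.442%.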

Other observations

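The site in this part was chosen after its values had been seen. Outside the receptor segments, 1 hotspot was shared by the RSSJ-chr1-12S and cRSS-chr1 libraries. It lay at chromosome 6 positions 70701770 to 70701786, 25.0 kb past the end of Igkc, the kappa constant segment, and held 3 and 5 junctions, against 0 in the IgH-AB library. The full heptamer CACAGTG lay beside it on the minus strand, with 6 of 9 nonamer bases matched at a 23-base spacer, which 5.17% of random CAC sites reached. A kappa-deleting element, an RSS downstream of Igkc, is known background for this region.

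In the RSSJ-chr1-12S library the bait reads ended near an RSS in the construct, GGTTTTTGTTCCAGTCTGTAGCACTGTG, with a 12-base spacer, and 559 of the junctions had a bait end within 10 bp of its heptamer's end.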
